A study of Mus musculus with 6 samples.

How the data were processed

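Chromatin accessibility was measured by ATAC-seq in microglia (MG) and bone marrow derived macrophages (BMDM) sorted from SB28 mouse brain tumours, with 3 libraries per group. Groups and replicate numbers were taken from the labels. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Per the labels, lysed cells were treated with a Nextera Tn5 kit and the tagmented DNA was amplified by PCR. Per the submitters' processing notes, the tools were cutadapt 1.8.1, Bowtie2 2.4.1, MACS2 2.1.1.20160309, ChIPseeker 1.32.1 and DESeq2 1.36.0, with the genome build mm10, and the authors used them before deposit. Their settings, any shift of reads for the transposase and the removal of duplicates are not given in the sources used here. The MACS2 peak names show calls on paired-end fragments of 1 library per list.

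The authors deposited 1 table over all peaks and 1 peak list per library. The table's library columns hold log2 values, variance-stabilized by the authors, and per the file headers its fold change columns are log2 too. The authors' deposited table also holds each peak's mean normalized signal, p-value and adjusted p-value. In the deposited peak lists each peak has a fold enrichment over the caller's local background and a −log10 p and −log10 q, which are the authors' values and were used only to rank or filter peaks within a list. Another 8 columns of per-sample values matched no sample of the series and were not used. Of 93084 lines 155 repeated a peak for a second gene identifier, 65 distinct peaks had no annotation, and 92864 peaks were used. Gene symbols, coordinates and annotation classes are those of the deposited table (mm10).

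The inverse of the stabilizing transformation gave normalized counts whose mean differed from the deposited mean by at most 2.4e-06 of its value. Multiplied by the size factors they gave whole reads (within 0.02 read) for at least 99.999% of peaks in each library. Reads in peaks ranged from 4913267 in BMDM 3 to 23608150 in MG 2. The limit that 3 counts allow was 1.64 normalized counts in MG 2 and 5.95 in BMDM 1. These limits cover counting error only, and PCR reads are not independent molecules. Bootstrap intervals cover the choice of promoters and exact intervals treat peaks as units, so neither covers the spread between libraries. Replicates differed by 6.28 to 45.9 times the counting variance. Each of the 6 peak lists matched its own table column best after centring, and 5 did without centring.

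Tests were planned for counts, with limma for normalized values. Since the deposited columns are normalized, limma 3.58.1 (R 4.3.3) was fitted with a trend to log2(normalized count + 1) with the authors' size factors, and fold changes on this scale understate the change of low peaks. A mean normalized count of at least 10 was required, a filter set before calls were compared, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Counts were tested per peak, per gene summed over peaks within 100 kb of the start site, and per gene summed over promoter peaks. The gene value counts every peak annotated to a gene, so it is not a measure of its promoter alone. The variance that limma shares across features took nearly all the weight at promoters, so that those p-values hardly use each promoter's own spread: 25.1% of the promoters called higher in MG had overlapping groups, against 5.16% of genes. That variance also took nearly all the weight for genes without MG 1, MG 2 or MG 3, without MG 2 and 3 and with the replicate block. For peaks it did so without MG 1 and without MG 2 and 3. On simulated data of the same depth the test recovered 8.08% of peaks with a 2-fold change and 71% with a 4-fold change, 51% and 100% of genes, and 35% and 96% of promoters, with 1, 10 and 8 unchanged features called. The simulation gave all features of a kind the same spread beyond counting error and no deviation shared within a library. Its rates of recovery and of false calls therefore need not hold for the real libraries.

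The 20 gene lists, the naming rule, the groups, the tests and most alternatives were fixed before the data were examined. The lists cover identity of microglia and of monocytes and macrophages, sort markers, glycolysis, oxidative phosphorylation, immunosuppressive mediators, PERK signalling, hypoxia, lysine acyltransferases, antigen presentation, interferon, inflammatory cytokines, lipid handling, adhesion, myeloid transcription factors, and neutrophil, dendritic, lymphoid, neural and glial, and endothelial cells. They were tested with camera at a preset correlation of 0.01, with an estimated one, and with fry, which tests against no change. Named are the 8 genes with the largest change in each direction past the threshold whose mean exceeds the median gene and whose groups do not overlap, without Rik, Gm and microRNA names; some genes that meet the rule are not reported here. The up to 4 members of each list with the smallest p, 14 genes fixed in advance and the 5 peaks with the smallest p per direction complete the rule, whose level was read here as the log2 mean normalized count. Peak lists were compared with bedtools 2.31.1 at an overlap of 1 base, and with exact permutation tests (scipy 1.17.1).

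Alternatives were library totals, loess, pseudocounts of 0.1 and 10, no filter, an absolute log2 fold change of at least 1, no limit of distance, promoter peaks alone, a stricter −log10 q of at least 5, a replicate block and leaving out each library. Chosen after seeing the data were TMM factors and voom on the recovered reads, array weights, robust variance moderation, the deposited stabilized values, and leaving out MG 2 and 3 together, which leaves 1 MG library and a spread from BMDM alone. Differences of genes are given relative to the median gene, but p-values test them before that shift. Count models, motif searches and checks of GC content were not run.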

Results

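ATAC-seq, in which the Tn5 transposase places sequencing adapters in open chromatin, was applied to myeloid cells sorted from brain tumours that the mouse glioma line SB28 formed in mice. Microglia (MG), the resident macrophages of the brain, were taken as F4/80+ CD11b+ cells with low CD45 and low or absent CD49d. Bone marrow derived macrophages (BMDM) were taken as F4/80+ CD11b+ CD45+ cells with high CD49d, and both gates kept cells with low or absent LY6C and without LY6G. Each group had 3 libraries. Reads in peaks numbered 19256080, 23608150 and 12538078 in MG 1, 2 and 3 and 7168950, 19731950 and 4913267 in BMDM 1, 2 and 3, so that the median peak held between 20 and 90 reads. Across peaks, log2 values correlated at 0.756 to 0.935 within MG, at 0.905 to 0.937 within BMDM and at 0.694 to 0.860 between the groups. MG 1 correlated at 0.892 with MG 3, at 0.839 to 0.860 with the BMDM libraries and at 0.756 with MG 2. On the first principal component, with 49.8% of the variance, MG 1 (-76.1) lay within the range of the BMDM libraries (-192 to -4.82), apart from MG 2 and 3 (260 and 155). On the second, with 31.4%, MG 1 lay at -252 and the other libraries between -65.3 and 117.

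The comparison of BMDM with MG asks, per the series text, how the metabolism of these cells bears on their gene expression and function. Summed over the peaks within 100 kb of each transcription start site, the gene with the largest increase in BMDM under the naming rule was Il2rb, which encodes the beta chain of the interleukin 2 receptor. Its normalized count was 737 ± 130 in BMDM and 215 ± 125 in MG (SD, n = 3 each), a log2 difference of 2.24 ± 0.39 (SE) relative to the median gene (limma adjusted p = 0.0104). Here and below, p-values test the difference before that shift, which was 1.97 for Il2rb. Its rank rests on MG 1, with 84.1 counts against 333 and 228 in MG 2 and 3: without MG 1 its difference was 1.59, below that of Il1rn (2.06). Il1rn, the interleukin 1 receptor antagonist, rose by 2.1 ± 0.31 (adjusted p = 0.00614), and Cybb, the catalytic subunit of the phagocyte NADPH oxidase, by 1.98 ± 0.34 (adjusted p = 0.00998). Gda, a guanine deaminase, rose by 2.04, Alpk2 by 2.02, the transporter gene Slco3a1 by 1.96, and the G protein-coupled receptor gene Gpr55 by 1.91. In the other direction Has2, a hyaluronan synthase, had 97.5 ± 33.1 normalized counts in BMDM and 959 ± 811 in MG, and fell by 2.5 ± 0.59 (adjusted p = 0.0142). Tcim fell by 2.29 ± 0.35, the secreted protease gene Adamts1 by 2.03 ± 0.36 and Nova1, a neuronal splicing regulator, by 1.92 ± 0.29 (adjusted p = 0.00439, 0.00478 and 0.00371). Fam171a1 fell by 1.78, the splicing regulator Rbfox2 by 1.71, Nav3 by 1.68 and the tubulin gene Tubb2b by 1.65. Has2 and Rbfox2 had their highest counts in MG 2 (1781 and 2169) and their lowest MG counts in MG 1 (159 and 566). Without MG 2 and 3, a fit with 1 MG library in which only BMDM gives the spread, adjusted p was 0.494 for Has2, 0.316 for Rbfox2, 0.117 for Gpr55, 0.0888 for Fam171a1, 0.0865 for Nav3, 0.0632 for Alpk2 and 0.0531 for Cybb. The differences of Has2 and Rbfox2 shrank there to -0.38 and -0.58 and those of Fam171a1 and Nav3 to -0.85 and -1.20, while Gpr55, Alpk2 and Cybb kept 1.87, 2.32 and 2.04. Without BMDM 1 it was 0.0669 for Cybb, 0.0505 for Gpr55 and 0.0517 for Has2, and without BMDM 3 it was 0.0646 for Il2rb and 0.0770 for Has2. With library totals Il2rb, Has2, Fam171a1 and Rbfox2 did not pass (0.0624, 0.133, 0.104 and 0.1), and with loess Has2, Fam171a1 and Rbfox2 did not (0.0937, 0.0662 and 0.0883).

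**Figure D1:**
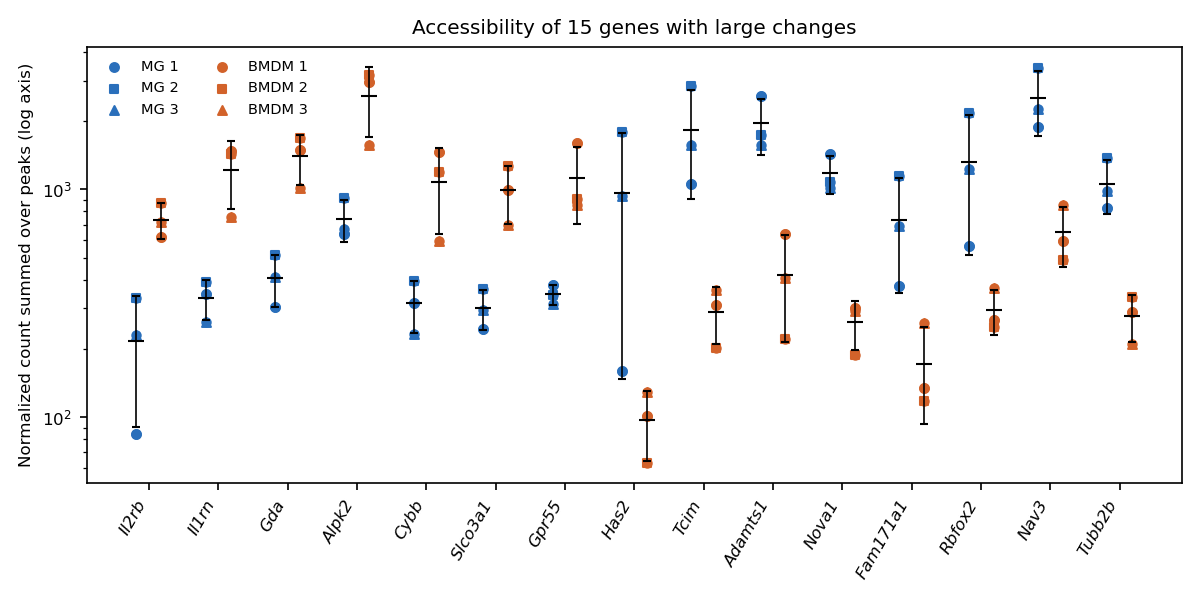
Summed normalized counts (log axis) of 15 genes with large changes named under the rule, the 7 higher in BMDM on the left and the 8 higher in MG on the right. Each point is a library, and each bar shows the mean ± SD of 3 libraries. The groups do not overlap in these 15 genes because the naming rule required it, and Has2 spans 159 to 1781 within MG.

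Over the 18246 genes tested, 391 were higher in BMDM and 640 higher in MG (limma, adjusted p under 0.05). The median gene differed by -0.27 (log2), a shift that was -0.08 with library totals, -0.03 with loess and -0.30 with TMM factors. Changes of single genes are therefore given relative to the median gene, although their p-values test the difference before that shift, so that calls depend on the scaling. The split between the directions followed the scaling, with 562 higher in BMDM and 251 higher in MG on library totals, and 1117 and 397 with loess. The groups did not overlap in 28.4% of genes, against 10% by chance for 3 and 3 libraries. The counts changed when single libraries were left out, which also leaves fewer libraries. Without BMDM 2, limma called 0 genes (lowest adjusted p = 0.0880), with 2845 genes at an unadjusted p under 0.05; with all libraries, voom called 277 and 303. Without BMDM 1 the counts were 79 and 102, without MG 3 they were 189 and 304, and without MG 1 they were 730 and 2246. Without MG 2, 611 genes were higher in BMDM, and without BMDM 3, 338 were higher in MG. The fits without MG 1, MG 2 or MG 3 also relied more on the variance shared across genes. Their total degrees of freedom were 54740, 54740 and 113, against 16.95 with all libraries. Those counts therefore do not show the effect of the library alone. Each gene described here as having risen or fallen had an adjusted p of 0.0880 or more without BMDM 2.

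Of 33 measured genes of monocyte and macrophage identity 10 rose in BMDM and 0 fell, and 16 rose with p adjusted over the list alone. As a list they passed camera at a preset correlation of 0.01 but not with an estimated one (adjusted p = 0.484). Fry, which tests a list against no change rather than against other genes, gave 0.193, and the median of the neutrophil markers was higher still (1.23 against 1.13). Clec4e, a C-type lectin receptor of myeloid cells, rose by 2.73 ± 0.32 (632 ± 226 normalized counts in BMDM and 109 ± 11.1 in MG, n = 3 each; limma adjusted p = 0.00354). F10, which encodes coagulation factor X, rose by 2.4, haptoglobin (Hp) by 2.29 and Ly6c2 by 1.99. Ccr2, the chemokine receptor of inflammatory monocytes, had 387 ± 91.9 counts in BMDM and 290 ± 27.8 in MG, a difference of 0.66 ± 0.28 that did not pass (adjusted p = 0.435). Among the genes of the sort markers, which are no independent evidence, 3 of 6 rose, also over the list alone: Ly6c2, Itga4 (CD49d) by 1.48 ± 0.31 (1818 ± 695 and 752 ± 75.0 counts; adjusted p = 0.0337) and Ly6g by 1.75. Ptprc (CD45) differed by 0.84 ± 0.36 (adjusted p = 0.368). In the adhesion and integrin list 3 of 24 rose, with the same number over the list alone. Among them were Itga4, and Itgal by 1.31. The difference of Cd44, a hyaluronan receptor, was 1.13 ± 0.40 (adjusted p = 0.215). Loess gave 19 risen monocyte genes and 8 risen adhesion genes, and voom 7 and 1, without Itga4 and Itgal. Without BMDM 1 and without BMDM 2 the risen members numbered 4 and 0 for monocyte identity, 0 and 0 for the sort markers and 1 and 0 for adhesion. Without MG 3 the sort markers and adhesion kept 1 each.

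Of 36 measured immunosuppressive mediators 6 rose in BMDM and 0 fell (8 risen over the list alone). This list too passed camera at a preset correlation but not with an estimated one (adjusted p = 0.575), and against no change fry gave 0.380. Beside Il1rn these were Trem1, an activating myeloid receptor, with a rise of 2.05 ± 0.32 (limma adjusted p = 0.00725), Il10, Arg2, Pdcd1lg2 and Cd163. Il10, an anti-inflammatory cytokine gene, had 1901 ± 652 counts in BMDM and 633 ± 86.8 in MG (n = 3 each), a rise of 1.8 ± 0.32 (adjusted p = 0.0122). Arg2, the mitochondrial arginase, rose by 1.59 (adjusted p = 0.0249). Arg1 differed by 0.85 ± 0.33 (adjusted p = 0.316) and Cd274, which encodes PD-L1, by 1.09 ± 0.30 (adjusted p = 0.123). In Arg1, 1 of 7 single peaks was called higher in BMDM, at chromosome 10, 24931609 to 24931827 (mm10), an intergenic site at -4125 bp from the start site, with 71.1 ± 43.7 counts in BMDM and 9.98 ± 1.51 in MG (adjusted p = 0.0264). In Cd274, 3 of 6 peaks were called, in an intron, in an exon and in the promoter class 1169 bp from the start site. They rose by 2.04, 2.06 and 1.62 relative to the median peak. The largest peak of the locus, at the start site (chromosome 19, 29366331 to 29367724), did not pass. It had means of 539 counts in BMDM and 474 in MG (limma adjusted p = 0.810). Arg2 had 0.0654 without MG 3 and 0.119 without BMDM 1. Cd274 passed with library totals (adjusted p = 0.0138), with loess (0.00739) and without BMDM 3 (0.0268). The risen members of the list numbered 2 without BMDM 1, 0 without BMDM 2 and 3 without MG 3, but 8 with library totals, 11 with loess and 9 without BMDM 3. The median of the list (0.63) lay below those of the neutrophil markers (1.23) and of the T, NK and B cell markers (0.86). For Il10 adjusted p was 0.0678 without BMDM 1, 0.132 without BMDM 2 and 0.275 in the fit with MG 1 as the only MG library.

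Of the 12 peaks annotated to Il10 on chromosome 1, 7 were called higher in BMDM and 0 higher in MG. The peak with the smallest p lay in the promoter class at 131022702 to 131023131 (mm10), 2857 bp from the start site, and rose from a mean of 33.4 to 165 counts (2.43 relative to the median peak; limma adjusted p = 0.0260). Distal peaks at 131000511 to 131000763 and 130996284 to 130996595 rose by 2.60 and 2.85. The largest promoter peak of the locus, at 131020709 to 131021813, had means of 152 and 435 counts and did not pass (adjusted p = 0.0583). Without MG 3, BMDM 1 or BMDM 2, no peak in the genome passed.

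**Figure D2:**
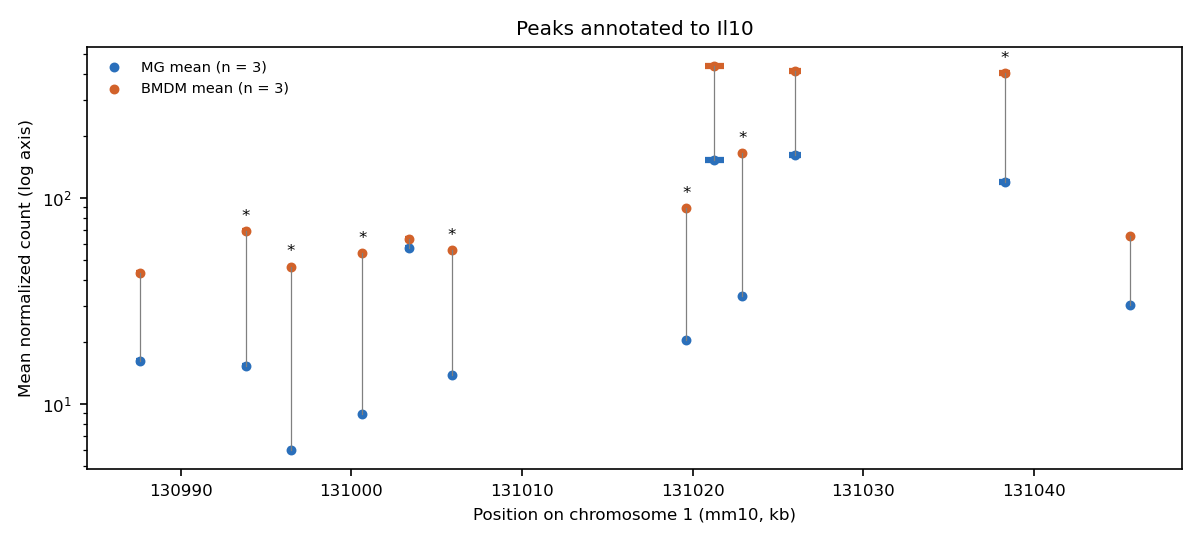
The 12 peaks annotated to Il10, by position on chromosome 1 (mm10, kb) and mean normalized count (log axis) of MG and BMDM (3 libraries each). An asterisk marks the 7 peaks with a limma adjusted p under 0.05; the BMDM mean is the higher at all 12 peaks, and the largest means are 435 and 413 counts in BMDM.

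Genes of microglial identity were more open in MG in 4 of 31 measured members, with 0 more open in BMDM (5 and 0 over the list alone). As a list they passed camera at a preset correlation (adjusted p = 0.00697) but not with an estimated one (0.742) or without MG 1 (0.675). Neural and glial markers moved the same way and further (median -1.02 against -0.22), and Sparc and Olfml3 had their highest counts in MG 2 (1422 and 1984), the library in which those markers were highest. As a list, however, microglial identity was highest in MG 1. Its median log2 value less each gene's mean was 0.73, -0.14 and 0.13 in MG 1, 2 and 3. In BMDM 1, 2 and 3 it was -0.08, -0.21 and -0.55. The neural and glial list had -0.21 in MG 1 and 1.22 in MG 2. Sall1, a transcription factor of microglial identity, had 342 ± 106 counts in BMDM and 1349 ± 759 in MG (n = 3 each) and fell by 1.60 ± 0.37 relative to the median gene (limma adjusted p = 0.0102). Its promoter peak, at chromosome 8, 89042171 to 89044360 (mm10), fell by 2.05 relative to the median peak, with counts of 1740, 464 and 919 in MG and 315, 149 and 165 in BMDM. Sall3 fell by 1.22 ± 0.28 (adjusted p = 0.00773), Sparc, a matricellular protein gene, by 1.11 and Olfml3 by 1.02. P2ry12, the purinergic receptor of resident microglia, differed by -0.48 ± 0.32 (adjusted p = 0.190). Of its 12 peaks 1 was called, in the promoter at chromosome 3, 59262767 to 59263161, and fell by 1.2 (adjusted p = 0.0465). Tmem119 had 1162 ± 254 and 1269 ± 132 counts, a difference of 0.12 ± 0.29 relative to the median gene (adjusted p = 0.798), and its unscaled sign flipped with the scaling. Its promoter alone, however, fell by 1.22 ± 0.34 relative to the median promoter, with 102 ± 13.2 counts in BMDM and 297 ± 24.9 in MG (adjusted p = 0.000206). With library totals 3 microglial genes fell, but Sall1, Sparc and Olfml3 did not pass (adjusted p = 0.0541, 0.103 and 0.0898), and with loess 5 fell and 1 rose, without Sparc and Olfml3 (0.0968 and 0.0959). With MG 1 as the only MG library 2 passed, and adjusted p was 0.302 for Sparc and 0.528 for Olfml3. Without BMDM 1, BMDM 2 and BMDM 3 the counts were 2, 0 and 2, Olfml3 had 0.0733 without MG 2, and Sall1 had 0.0523 without BMDM 3, and the promoter peaks were lost without MG 3, BMDM 1 or BMDM 2.

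For the metabolic genes that the series text is about, few members passed. In glycolysis and lactate handling 0 of 27 rose and 2 fell, also over the list alone. These were Ldhb, a lactate dehydrogenase subunit, by 1.01 ± 0.28 (269 ± 40.6 counts in BMDM and 660 ± 133 in MG, n = 3 each; limma adjusted p = 0.0147), and the monocarboxylate transporter Slc16a1 by 0.72 ± 0.28 (adjusted p = 0.0451 for the difference of -0.99 before the shift). Slc2a1, the glucose transporter GLUT1, had 2302 ± 657 counts in BMDM and 2810 ± 502 in MG, a difference of -0.05 ± 0.34 relative to the median gene (adjusted p = 0.618). Ldha differed by 0.14 ± 0.30 (adjusted p = 0.830), with an unscaled sign that flipped with the scaling, Pdk3 by -0.49 and Eno2 by -0.43. With library totals 2 members rose and 1 fell, Ldhb losing its call (adjusted p = 0.0722), and with loess 2 rose and 2 fell. Without BMDM 1 or BMDM 2 none passed, Ldhb having an adjusted p of 0.0911 and 0.0988. Without MG 2 or MG 3 only Ldhb did, since Slc16a1 had 0.117 and 0.149, and 0.0606 without MG 1. With MG 1 as the only MG library none passed (0.193 for Ldhb and 0.366 for Slc16a1), and Slc16a1 lost its call with voom. In the hypoxia list 1 of 23 rose and 1 fell (1 and 2 over the list alone). The stress gene Ndrg1 rose by 1.43 (adjusted p = 0.0354) and Ppp1r3c, a glycogen-targeting phosphatase subunit, fell by 1.40 (adjusted p = 0.0214). The difference of Adm was -0.58 (adjusted p = 0.0728), of Car12 0.95 and of Hif1a 0.45 ± 0.31 (adjusted p = 0.767). Both hypoxia calls ended without MG 3, BMDM 1 or BMDM 2 (adjusted p from 0.0828 to 0.230) and with MG 1 as the only MG library. Ppp1r3c lost its call with library totals (0.134) and Ndrg1 with voom, while loess gave 3 risen and 2 fallen genes.

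No gene of oxidative phosphorylation and the TCA cycle passed, limma and voom both calling 0 of 41 (also over the list alone), with 2 lower in BMDM at an unadjusted p under 0.05. Differences relative to the median gene were -0.40 for Ndufa9, -0.34 for Suclg2, -0.35 for Ndufb8 and -0.30 for Cox6c. In the list of the PERK kinase and the unfolded protein response limma and voom called 0 of 23, also over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05. Eif2ak3, which encodes PERK, differed by 0.13 ± 0.34 (2500 ± 791 counts in BMDM and 2661 ± 269 in MG, n = 3 each; limma adjusted p = 0.847), with an unscaled sign that flipped with the scaling, Trib3 by -0.52, Slc7a11 by 1.07, Psat1 by -0.24 and Nupr1 by 0.71. Library totals gave 1 risen gene of this list and loess 2, Slc7a11 passing in both (adjusted p = 0.0113 and 0.00478). Atf4 was not analysed here. Among lysine acyltransferases and deacylases, the enzymes that write and remove acyl marks on histones, limma and voom called 0 of 27 (also over the list alone), with 1 higher and 4 lower at an unadjusted p under 0.05. Ep300 differed by 0.04 ± 0.32 (adjusted p = 0.709), Hdac11 by -0.64 (adjusted p = 0.0541), Hdac5 and Hdac9 by -0.48 each, and Sirt3 by 1.29 (adjusted p = 0.116). Library totals and loess gave 1 risen gene each. TMM factors, robust variance moderation and leaving out MG 1 gave 1 fallen gene each, and the replicate block gave 1 risen and 3 fallen. The promoters of Hdac5 and Hdac11 fell by 0.97 and by 0.76 relative to the median promoter (adjusted p = 0.00156 and 0.0104), and each gene had 1 peak called higher in MG.

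Among interferon response genes 2 of 25 rose, also over the list alone: Oasl2 by 1.34 ± 0.28 and Oas2 by 1.56 ± 0.36 (limma adjusted p = 0.0358 and 0.0473). Rsad2 differed by 1.21 (adjusted p = 0.136) and Cxcl9, at 30.4 and 9.44 counts, by 2.14 (adjusted p = 0.153). For inflammatory cytokines and chemokines limma and voom called 0 of 22, with 4 higher in BMDM at an unadjusted p under 0.05 and 3 over the list alone. Those were Cxcl1, Cxcl2 and Il23a, with differences of 1.37, 1.55 and 1.30 (adjusted p = 0.0599, 0.0681 and 0.0801), while Ccl7 had 1.08. In antigen presentation limma and voom called 0 of 20, with 1 at an unadjusted p under 0.05 and 0 over the list alone. Ciita, Cd40, H2-Aa and H2-Ab1 differed by 1.02, 0.91, 0.91 and 0.86 (adjusted p from 0.177 to 0.327). In the list of lipid handling and disease-associated microglia 1 of 29 rose, also over the list alone, the fatty acid binding protein gene Fabp4 by 1.90 (adjusted p = 0.0362), and Igf1, Clec7a and Cd36 differed by 1.14, 1.08 and 1.08. Of 46 myeloid transcription factors Runx2 rose by 1.34 (adjusted p = 0.0384) and Sall1 and Sall3 fell, with the same count over the list alone; Bhlhe41 differed by -0.66 (adjusted p = 0.0679). Scaling moved these counts, loess giving 4 risen genes in each of the interferon, inflammatory, antigen and lipid lists, and 4 risen and 7 fallen transcription factors. Library totals ended the calls of Oas2 and Fabp4 (0.0981 and 0.0847), and voom those of Oasl2, Oas2, Fabp4 and Runx2, with 0 risen genes in the interferon, lipid and transcription factor lists. Oasl2, Oas2, Fabp4 and Runx2 lost their calls without MG 3, BMDM 1 or BMDM 2 (adjusted p from 0.0982 to 0.265), Oas2 and Fabp4 also without BMDM 3 (0.0985 and 0.0861) and Runx2 without MG 2 (0.11). With TMM factors and with no limit of distance the interferon list kept 1 risen gene. The inflammatory list gave 4 risen genes without MG 1, 2 without MG 2 and 3 without BMDM 3, the interferon list 5 without MG 2, the lipid list 2 without MG 1 and 2 without MG 2, and the transcription factors 2 without MG 1 and 2 without BMDM 3.

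Some markers of cell types outside the sorted populations differed between the groups. Of 18 neural and glial markers 9 fell and 1 rose (10 and 1 over the list alone). Snap25, a neuronal SNARE protein gene, fell by 1.99 ± 0.36 (45.5 ± 16.2 counts in BMDM and 213 ± 17.5 in MG, n = 3 each; limma adjusted p = 0.00516), the myelin gene Mog by 1.53, the astrocyte glutamate transporter gene Slc1a3 by 1.56 and Nes by 1.38. The exception was Slc1a2, also an astrocyte glutamate transporter gene, which rose by 1.60 (adjusted p = 0.0173) and was named after its value was seen. Per library, the list's median log2 value less each gene's mean was -0.21 in MG 1, 1.22 in MG 2, 0.74 in MG 3 and -0.78, -0.78 and -0.38 in BMDM 1, 2 and 3. With MG 1 as the only MG library 2 of these genes fell and 0 rose; library totals gave 3 fallen and loess 5. Of 18 T, NK and B cell markers 2 rose (6 over the list alone), the cytotoxic granule genes Gzmb by 1.85 and Prf1 by 1.41 (adjusted p = 0.0147 and 0.0309). Cd3e differed by 1.52 ± 0.38 (adjusted p = 0.0611) and Ms4a1 by 1.4. Of 9 neutrophil markers 2 rose (5 over the list alone), Ly6g and the collagenase gene Mmp8 by 1.75 and 1.72 (adjusted p = 0.0362 and 0.0484), and Mpo and Ltf differed by 1.24 and 1.10. Of 10 dendritic cell markers 1 rose, also over the list alone, Dpp4 by 1.87 (adjusted p = 0.0142); Ccr7, Tcf4 and Flt3 differed by 0.92, -0.46 and 0.82. Of 13 endothelial and mural markers Erg rose by 1.59 and Cldn5 and Col1a1 fell by 0.93 and by 0.87, the same count as over the list alone, while Acta2 differed by 1.04. Library totals gave 3 risen and 1 fallen endothelial and mural markers and loess 3 and 0. With library totals 1 lymphoid, 2 neutrophil and 2 dendritic markers rose, and with loess 5, 4 and 3. Col1a1 lost its call with library totals, loess (adjusted p = 0.145 and 0.149) and voom, and Cldn5 with loess (0.0607). Library totals also ended the calls of Ly6g, Mmp8, Gzmb, Dpp4 and Nes (0.0537, 0.0697, 0.0513, 0.0583 and 0.0653), and loess, TMM factors and voom that of Mmp8 (0.0519 with loess).

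**Figure D3:**
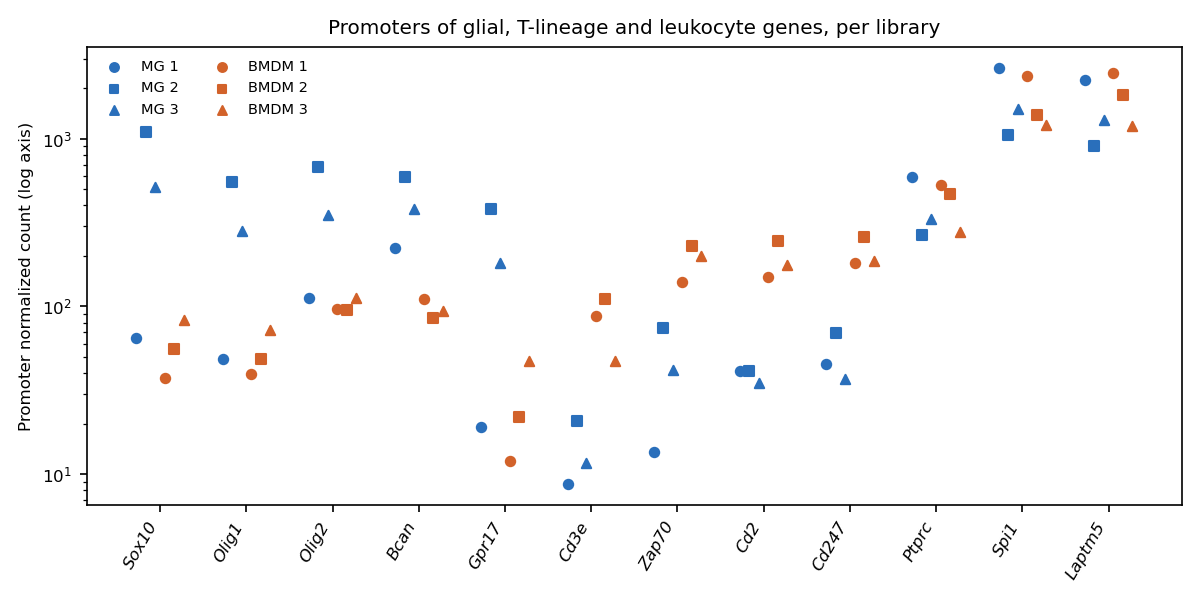
Promoter counts (normalized, log axis) of 12 genes in each of the 6 libraries, with oligodendroglial, T cell and pan-leukocyte genes named after their values were seen. Sox10 had 65.1 counts in MG 1, 1102 in MG 2 and 518 in MG 3, and Cd3e 8.73, 20.8 and 11.7 in MG and 87.3, 110 and 47.1 in BMDM.

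Those counts of other cell types also changed when single libraries were left out. Without BMDM 1, 5 neural and glial genes fell and 0 rose, 1 lymphoid gene rose, and 0 neutrophil and 0 endothelial genes passed. Without BMDM 2 limma called 0 genes of any list, although the differences of Snap25, Mog and Gzmb were then still -1.65, -1.28 and 1.59. Without BMDM 3 the dendritic and endothelial lists gave 0 and the neutrophil and lymphoid lists 1 each. Without MG 1, 4 lymphoid genes rose and 3 endothelial genes fell. Without MG 2 the lymphoid list gave 6 risen genes and the endothelial list 0 risen and 1 fallen. Without MG 3 the lymphoid list gave 1 risen gene, the neutrophil list 0, the endothelial list 1 risen and 0 fallen, and Slc1a2 did not pass.

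Tested against all other genes with camera at a preset correlation of 0.01, 10 of the 20 lists were higher in BMDM and 2 higher in MG. None passed with an estimated correlation, where the lowest adjusted p was 0.484. The largest list medians relative to the median gene were 1.23 for neutrophil markers, 1.16 for sort markers, 1.13 for monocyte and macrophage identity (camera adjusted p = 1.8e-18) and 0.86 for T, NK and B cell markers. Immunosuppressive mediators (0.63), inflammatory cytokines (0.61), adhesion (0.53), antigen presentation (0.45), lipid handling (0.42) and interferon response (0.36) were higher too. Neural and glial markers (-1.02; adjusted p = 5.6e-05) and microglial identity (-0.22; adjusted p = 0.00697) were higher in MG. Glycolysis and lactate (0.12), the PERK list (0.13), hypoxia (0.10), myeloid transcription factors (0.11), dendritic markers (0.03), oxidative phosphorylation (0.03), lysine acyltransferases (-0.04) and endothelial markers (-0.05) did not pass (adjusted p from 0.275 to 0.964). For oxidative phosphorylation and endothelial markers camera's direction was opposite to the sign of that median. With an estimated correlation adjusted p was 0.484 for monocyte, sort and neutrophil markers, 0.545 for T, NK and B cell markers, 0.575 for immunosuppressive mediators and for neural and glial markers, 0.686 for the other lists higher in BMDM and 0.742 for microglial identity. Against no change, the lowest adjusted p with fry was 0.163. Without MG 2 and 3, which leaves 1 MG library and a spread from BMDM alone, 6 lists were higher in BMDM and 1 in MG. Without MG 1 microglial identity had an adjusted p of 0.675. Another grouping of the 6 libraries, MG 1, MG 2 and BMDM 3 against the rest, called 13 lists.

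**Figure D4:**
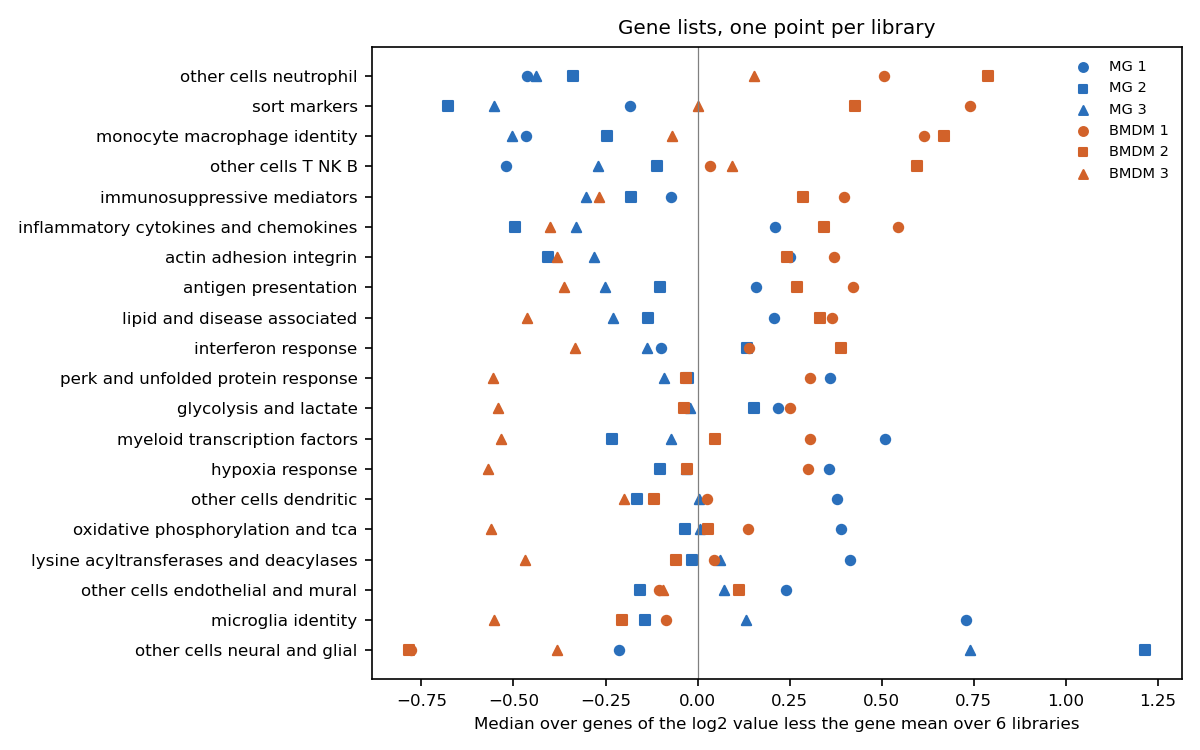
Median over the genes of each list of the log2 value in a library less that gene's mean over the 6 libraries, with 1 point per library (MG blue, BMDM orange) and the lists ordered by their median difference between the groups. Monocyte and macrophage identity lies at -0.07 to 0.67 in BMDM and -0.50 to -0.25 in MG, and neural and glial markers reach 1.22 in MG 2 and 0.74 in MG 3 but -0.21 in MG 1.

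At single peaks, the 5 smallest p-values among those higher in BMDM belonged to distal and intronic sites. A distal intergenic peak at chromosome 6, 123280191 to 123281628 (mm10), annotated to Clec4e, had 224 ± 79.7 normalized counts in BMDM and 20.7 ± 2.85 in MG (n = 3 each), a rise of 3.46 ± 0.35 relative to the median peak (limma adjusted p = 0.0260, which all 10 peaks named here share). A distal peak at chromosome 14, 121829885 to 121830468, annotated to Dock9, rose by 3.46. A distal peak at chromosome 11, 99142547 to 99143718, annotated to Ccr7, a chemokine receptor of migrating leukocytes, rose by 2.84. An intronic peak of Nsmce1 at chromosome 7, 125482044 to 125483045, rose by 2.83, and one of Syk, a tyrosine kinase of immune receptor signalling, at chromosome 13, 52591846 to 52592204, by 3.42. Among the peaks higher in MG, 4 of the 5 with the smallest p were promoter peaks. Those of Smarcd3 (chromosome 5, 24604441 to 24605136), Neo1 (chromosome 9, 59035441 to 59037313), Tgfa (chromosome 6, 86194707 to 86195936) and Prox1os (chromosome 1, 190169945 to 190171045) fell in BMDM, with differences of -2.44, -2.35, -2.36 and -2.39. The remaining one, annotated to Ywhaz, was intergenic at chromosome 15, 36854756 to 36855995, and fell by 2.38. Of 87944 peaks tested, 4687 were higher in BMDM and 1352 higher in MG; the groups did not overlap in 29.9% of peaks, against 10% by chance. Library totals gave 7030 and 1136, and loess 6950 and 2305. Limma called 0 peaks without MG 3, without BMDM 1 or without BMDM 2, with 14430, 15862 and 14806 at an unadjusted p under 0.05, and voom called 0 with all libraries, with 21048 at that level. Without MG 1 the counts were 10603 and 11278, without MG 2 they were 8190 and 2528, without BMDM 3 they were 2030 and 413, and with MG 1 as the only MG library they were 7673 and 1762.

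The peaks higher in MG were more often promoters than those higher in BMDM. Of the MG peaks 53.3% (95% exact binomial interval 50.6 to 55.9) lay in promoters, of the BMDM peaks 17.7% (16.6 to 18.8) and of the peaks that did not pass 31.4%. The odds of a promoter were 5.31 times as high in the MG set as in the BMDM set (95% interval 4.65 to 6.06; Fisher's exact test, p = 4.5e-140), with peaks taken as units although they are not replicates. BMDM peaks lay more in introns (41.0% against 18.7%) and in intergenic DNA (33.6% against 20.3%). The odds ratio was 7.97 with library totals, 4.19 with loess and 3.34 among the calls of the authors' deposited test. It was 2.09 without MG 1, 3.23 without MG 2 and 8.06 without BMDM 3. Without MG 3, BMDM 1 or BMDM 2 no peak passed.

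Promoter accessibility per gene gave 419 genes higher in BMDM and 1397 higher in MG among 15249 tested (limma, adjusted p under 0.05). The promoter of Sall1 fell by 1.86 relative to the median promoter, with 226 ± 95.8 counts in BMDM and 1107 ± 693 in MG (n = 3 each), and that of Ldhb by 1.18. Promoters of Il10, Il1rn and Il2rb rose by 1.99, 2.05 and 2.81. The median promoter differed by -0.31 (log2). Library totals gave 360 and 575, and loess 752 and 461. In this fit the spread was estimated as nearly the same for every promoter, so that a wide spread in 1 gene counted little: of the 1397 MG calls, 340 had MG 1 at or below a BMDM library, Sox10 with 65.1 counts in MG 1 and 37.7, 55.7 and 83.3 in BMDM among them, named after its values were seen. With MG 1 as the only MG library the counts were 317 and 306. Without BMDM 3, which had the lowest read total, they were 269 and 547, without MG 3 178 and 496, without BMDM 1 227 and 824, without BMDM 2 154 and 843, and without MG 2, 751 were higher in MG.

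The authors' deposited table held a test of the same peaks, with 8414 higher in BMDM and 4994 higher in MG at an adjusted p under 0.05. All 6039 peaks that limma called were among those 13408, with the same sign, and 7232 of the peaks the authors called were tested and not called by limma. Log2 fold changes correlated at r = 0.982 across the 87944 peaks, which are not independent replicates. Of the 4994 peaks higher in MG in the authors' deposited table, 2165 (43.4%) had MG 1 at or below at least 1 BMDM library, and of the 1352 that limma called 0 had. The number of limma calls among the authors' was 12493 without MG 1, 2414 without BMDM 3 and 0 without MG 3, BMDM 1 or BMDM 2.

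Beside each peak the authors' deposited table gave a gene-level comparison of BMDM with MG, whose assay its header does not name. For 8661 genes with both values it called 365 higher in BMDM and 179 higher in MG. In the authors' deposited table Ly6c2 stood at 5.79 (log2), F10 at 5.66, Ccr2 at 4.98, Clec4e at 4.71, Il1rn at 3.24 and Adamts1 at -3.45, each with an adjusted p under 0.05 there. There Slc2a1 had 0.49 (adjusted p = 0.330), Ldha 1.13 (adjusted p = 0.0197), Ldhb -2.5 (adjusted p = 0.0423) and Cd274 1.05 (adjusted p = 0.302). Of the listed monocyte and macrophage genes with a value, 13 of 16 were called higher in BMDM, and of the microglial genes 5 of 10 were called higher in MG. Genes called both there and in accessibility numbered 102, with 67 higher in BMDM in both and 34 higher in MG in both, where independent lists would share 11.2 and 7.87. The exception, Adi1, named after its values were seen, was 1.33 at gene level and fell by 0.79 in accessibility. Over all 8661 genes the Spearman correlation was 0.265, and over the 544 genes called at gene level it was 0.733. Choosing genes by 1 of the 2 values compared can raise the correlation by itself, so 0.733 does not show closer agreement. Genes are also not independent replicates.

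The peak lists that the authors called per library held 50217, 70739 and 52566 peaks in MG and 33982, 52631 and 17741 in BMDM. The means were 57841 ± 11230 and 34785 ± 17460 (SD, n = 3 each), with p = 0.3 in a two-sided exact permutation test, which decides nothing since the smallest p that 3 against 3 libraries can give is 0.1. Median peak width was 543 ± 19.0 bp in MG and 508 ± 21.0 bp in BMDM (exact permutation p = 0.2). Merged over libraries, 4826 regions were found in all 3 MG lists and no BMDM list, and 89 in all 3 BMDM lists and no MG list. The 9 other splits of the libraries gave 268 on average and at most 1362 per side. With the same number of top-ranked peaks from every library the counts were 721 and 918, so that their order followed the lengths of the lists. Without MG 1 the first count was 12053 and without BMDM 2 it was 11790; the second was 163 without MG 2, 250 without BMDM 1 and 1318 without BMDM 3. The Jaccard index was 0.502 on average within groups and 0.406 between them (one-sided exact permutation p = 0.1, the smallest possible).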

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

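TMM factors, voom, array weights, the deposited stabilized values, robust variance moderation and leaving out MG 2 and 3 together were chosen after seeing the data; the last leaves 1 MG library. No peak, gene or promoter called in 1 direction by the main fit (the authors' size factors, all libraries) was called in the other by another fit. Calls of the other fits were not compared with each other. The balance of the gene counts turned with library totals, loess and without MG 2 and 3, and that of the promoter counts with loess and without MG 2 and 3. Peaks higher in BMDM and in MG numbered 4687 and 1352; voom called 0 and 0, array weights, which did not converge, 23025 and 20730, the authors' deposited test 8414 and 4994, and loess 2305 in MG. Without MG 2 and 3, 7673 were higher in BMDM. Genes numbered 391 and 640; loess gave 1117 and 397, library totals 562 and 251, leaving out MG 2 and 3 438 and 254, and in MG voom gave 303 and promoter peaks alone 1397. Promoters numbered 419 and 1397; loess gave 752 and 461, leaving out MG 2 and 3 317 and 306, and in MG library totals gave 575 and voom 633. Lists numbered 10 and 2, against 6 and 1 without MG 2 and 3 and 0 and 0 with an estimated correlation. The same number of top-ranked peaks per library left 721 regions in all MG lists alone and 918 in all BMDM lists alone. The cause was not tested.

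Leaving out 1 library gave 0 to 10603 peaks higher in BMDM and 0 to 11278 in MG, 0 to 730 and 0 to 2246 genes, 154 to 503 and 496 to 1846 promoters, and 1 to 2 lists higher in MG. Limma calls among the authors' ranged from 0 to 12493, regions in all MG lists alone from 4835 to 12053 and in all BMDM lists alone from 98 to 1318. Libraries of the same number deviated together by correlations of 0.44, -0.06 and 0.36. With 3 libraries per group these values cannot decide whether the numbers pair the libraries. The main fit took them as unpaired, as planned. With the replicate block 9212 and 5215 peaks and 912 and 2333 genes were called. Of the 50 named genes past the threshold, library totals ended 17 calls, loess 8, voom 11 and leaving out BMDM 2 all 50, while both pseudocounts and no filter ended 0. Of the 50 others loess gained 22, library totals 14 and the replicate block 25. The 10 named peaks were lost with voom and without MG 3, BMDM 1 or BMDM 2. Planned count models, motif searches and GC checks were not run. With a 2-fold change 8.08% of simulated peaks were recovered.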

Other observations

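Further loci moved in the lists, outside the naming rule and chosen after their values were seen. Olig1, a transcription factor of the oligodendrocyte lineage, had 235 ± 67.8 counts in BMDM and 1880 ± 1661 in MG (n = 3 each) and fell by 2.11 ± 0.61 relative to the median gene (limma adjusted p = 0.0317). Sox2, a neural progenitor factor, fell by 2.03, Cspg4 by 1.45 and Pdgfra, a receptor of glial progenitors, by 0.96. Pdcd1lg2, which encodes PD-L2, rose by 1.49 ± 0.30 (adjusted p = 0.0282), the scavenger receptor gene Cd163 by 1.43 and the lectin receptor gene Clec12a by 1.76. Without BMDM 2, limma called 0 genes (lowest adjusted p = 0.0880), with 2845 at an unadjusted p under 0.05.

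All tests that follow were chosen after the result was seen, except the counts of splits for promoters and lists, and the 8 lists of promoters were drawn up once the data were known. Glial loci were open in MG 2 and 3. The median oligodendroglial promoter had 88.9, 460 and 316 counts in MG 1, 2 and 3 and the median astrocytic one 81.7, 207 and 120, but Mbp had 523, 503 and 392. The median neuronal promoter had 84.1, 208 and 123 counts, but neuronal promoters did not move as a set. Syt1, Tubb3, Neurod1 and Slc17a7 were higher in MG 2 and 3 than in MG 1. Nova1, Elavl3, Neurod2 and Gad1 were highest in MG 1, and Rbfox3 was about equal. Whether background reads were higher there cannot be decided. Oligodendroglial promoters rose in MG 2 over MG 1 by 1.63 more than lymphoid ones (log2, 95% bootstrap interval 0.595 to 2.86). But the lymphoid promoters were taken as closed, and Lck (777 counts), Cd6 (685) and Cd3d (420) were open in MG 1. Of those with low counts in MG 1, Zap70 and Bcl11b rose in MG 2 (to 74.9 and 80.4), while Thy1 and Gzmb fell (to 14.8 and 20.8). Depth is argued against, since oligodendroglial promoters lay 0.83 higher in MG 3, with fewer reads, than in MG 1 (0.325 to 1.85). Cells of the oligodendroglial lineage or tumour cells in the sort may contribute, although the F4/80+ CD11b+ gate would remove them. Pan-leukocyte promoters (1090, 503 and 643 counts) against ubiquitous ones (1376, 923 and 1004) were lower in MG 2 than in MG 1 by -0.55 (-0.812 to -0.381). In MG 3 they were lower than in MG 1 by -0.29 (-0.364 to -0.194). Both intervals lie below 0, but MG 3 fell just short of the -0.3 set after the data were seen, which keeps this open. MG 1 may equally be the library that stands apart, and no biological explanation was tested.

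BMDM 3 had a flat profile, with an SD of log2 over peaks of 1.47 against 1.99 in BMDM 2. Fewer reads alone would not flatten the profile: thinning BMDM 2 to the reads of BMDM 3 raised its SD from 1.99 to 2.1, which is 0.63 above that of BMDM 3. Thinning adds counting error, so the direction of this outcome was fixed in advance. More background reads may contribute: ubiquitous promoters were lower than in BMDM 1 and 2 by -0.80, and oligodendroglial and neuronal promoters were higher by 0.38, but that interval (-0.039 to 0.728) includes 0 and keeps it open. No biological explanation was tested.

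Lymphoid loci were open in BMDM, with median T cell promoters at 141, 228 and 178 counts in BMDM and 41.3, 69.4 and 41.8 in MG, and NK cell promoters at 102, 167 and 107 and 52.0, 34.4 and 46.7. B cell promoters lay at 76.4, 85.8 and 96.0 and 98.4, 106 and 88.4. Whether background reads were higher in BMDM cannot be decided. T cell promoters exceeded the B cell, oligodendroglial and neuronal ones by 1.22 (0.420 to 2.83) in BMDM over MG 1 alone. They exceeded the B cell ones by 1.5 (0.0424 to 2.46) over the mean of all MG libraries. But the promoters compared with were taken as closed, and Pdgfra (700 counts), Mbp (523) and Bank1 (256) were open in MG 1. Others, such as Gpr17 (19.0) and Blk (5.55), had low counts there. T or NK cells in the sort are a candidate explanation, although the F4/80+ CD11b+ gate would remove them. T cell promoters lay at least 0.97 above the MG mean in each BMDM library and 86.7% of members were higher, although the interval in BMDM 3 (-0.209 to 1.79) includes 0. These values restate the pattern itself, so they do not favour this explanation over others. The promoters of Zap70 and Nkg7, picked from these lists after their values were seen, had 141, 228 and 199 and 218, 296 and 217 counts in BMDM, and macrophages that open these loci themselves were not tested.

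The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. For peaks 1 split, the real one, gave as many calls (6039, highest other 0), for genes 1 (1031, highest other 521) and for promoters 1 (1816, highest other 418). For lists 3 splits gave as many (12, highest other 13).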
